A study of Mus musculus with 2 samples.

How the data were processed

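The deposited data came from 2 coronal mouse brain sections, 1 from a control pup and 1 from a pup with modelled intestinal perforation, imaged on a Xenium instrument. Per the labels, the model was started on postnatal day 5 and brains were taken after 48 h, and the sections were 5 micrometres thick. The submitters' processing notes name the genome build mm10. The versions of the decoding and segmentation software are not given in the sources used here. Groups were taken from the treatment label of each sample.

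For each section the authors deposited a matrix of transcript counts per panel feature and segmented cell, a table of cells and a table of decoded transcripts. The counts are whole numbers of decoded transcripts, not normalized, and equal the transcripts in the deposited table that lie inside a cell and have a quality value of at least 20. The quality value is a score per transcript, as deposited by the authors, and 76.8% of decoded transcripts in each section reached 20. The cell table gives cell positions and areas, which were read as micrometres and square micrometres because the file headers do not state the unit. Besides 298 genes, the panel holds 27 negative control probes, 41 negative control codewords and 175 unassigned codewords, which were used as background and left out of totals. No duplicate removal applies to imaging data of this kind, and transcripts in dense tissue can be assigned to a neighbouring cell.

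Cells with at least 10 panel counts were kept, which left out 46 control and 28 peritonitis cells. Counts of each gene were summed over the cells of a section or class and divided by the total of panel counts and scaled to 1000000 (CPM). The ratio of a pair of sums was given an exact 95% interval from the binomial split of the counts, and a share an exact Clopper-Pearson interval. Both cover counting error only, and no difference between animals, sections or planes. With 36886230 and 29799839 counts these intervals are narrow, so with 1 section per group the spread between animals, which was not measured, limits every comparison. Genes were compared where 1 or both sections reached 100 CPM, and described by a fixed size of 1.5-fold. Gene symbols and identifiers are those of the files. All 298 panel genes were matched to a gene table of GRCm38.p6, the assembly called mm10, 296 by symbol and 2 by a synonym, and gene coordinates come from that table.

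Cells of both sections were clustered together. Counts were scaled to the total per cell and log-transformed, and 30 principal components, 15 nearest neighbours and Leiden clustering at resolution 1 gave 44 clusters. A cluster took the class with most markers among its top 10 genes by fold over other cells, with at least 2 there and at least 3 markers detected at a mean of 0.1 counts per cell, and is called by that class with "-like". The minimum of 2 and the mean of 0.1 were set with the data at hand but before any cluster was named. A cluster whose 3 leading genes held none of its markers was left without a name, a rule set after seeing the data. It kept out clusters with 7.18% of control and 6.29% of peritonitis cells from the cortical glutamatergic class, 4.03% and 3.65% from the striatal class, and 0.189% and 0.355% from the fibroblast class. The cluster of the last, led by the macrophage genes Cd163, Msr1 and Lyz2, was not compared. The plan named neuroblast-like cells as a class to compare. No cluster took that name, and progenitor-like cells were compared in its place, a choice made after seeing the clusters. No doublet caller was run, since cells were segmented from images. Overlapping cells and misassigned transcripts play that part here, and transcripts over nuclei alone were used as an alternative.

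Within a class, genes were compared that had at least 100 counts in one or both sections and a class CPM at least that of the whole section in one or both, which leaves out many transcripts of neighbouring cells. The list medians within classes were taken over all members with at least 100 counts, and again over only those that meet both conditions, an alternative chosen after seeing the data. The text names the 8 highest and 8 lowest ratios over whole sections, except 1 of the latter that is not reported here, the 3 highest and 3 lowest per class, and of each list the 2 members with the highest levels and the 2 farthest from 1, from which examples were taken. Of 25 fixed lists, 20 of cell type markers and 5 of responses, those for choroid plexus and blood cells had no gene on the panel. A list is described by its median ratio and the percentile of its median log2 ratio among 10000 random lists, each member replaced by 1 of the 30 panel genes nearest in mean expression. The periventricular zone held cells within 150 micrometres of cells with at least 2 counts over the 2 ependymal genes on the panel that had at least 2 such cells within 50 micrometres.

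The comparisons, the gene lists, the rule for the genes named, the thresholds not listed otherwise here and a set of other settings were chosen before the data were examined. These settings were other scalings, count minimums and quality values, transcripts over nuclei, other clusterings, thinning to 50 counts, each side of a section, and other zone sizes and landmarks. Chosen after seeing the data were leaving out fields of view in which under 70% of transcripts reached quality 20, clustering without 26 differing genes, the cluster lining the ventricle as landmark, distance bands, microglia-like cells within and beyond 300 micrometres of it, tissue area as the squares of 100 micrometres that hold a cell, and microglia-like cells with at least 2 Siglech transcripts. So were 8 tissue regions, found by k-means on the clusters of the 100 nearest cells. In the 4 low-quality fields, whose lowest value was 48.1%, single genes were nearly missing. In 1 of them Olig1 had 30 counts against 2116 expected from the fields around it.

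The procedure was tested on simulated data. In 20 simulations of the whole-section comparison, with 298 genes, 60 of them changed and 279 compared, the intervals held the true ratio in 95.1% of cases and 0 unchanged genes passed 1.5-fold. Of genes changed 2-fold or 3-fold 100% passed, and of genes changed exactly 1.5-fold, which lie on the threshold, 45.0%. Of simulated cells of 10 classes with 400 cells each, 99.9% received their class. These cells were drawn from the mean profile of each named class, without spread within a class, transcripts of neighbouring cells or unnamed cells. Counts in the whole-section simulations were Poisson draws, the case the interval is built for. These results therefore check the code and do not measure the accuracy of classes or intervals in tissue. A shifted list stood at percentile 100 and lists without a shift at a median percentile of 45.1. The analysis used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, python-igraph 0.11.9 and leidenalg 0.10.2, and figures were drawn with matplotlib 3.10.9.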

Results

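Intestinal perforation, which spills gut contents into the abdomen and brings on peritonitis, was modelled in mouse pups on postnatal day 5, and brains were taken 48 h later. The title of the series names the subventricular zone, the germinal layer along the lateral ventricle, as the tissue of interest. Coronal sections of fixed, paraffin-embedded brain, 5 micrometres thick, were imaged with Xenium, an in situ method that decodes single transcripts of a chosen gene panel in intact tissue and assigns them to segmented cells. The panel held 298 genes, of which 248 belonged to a mouse brain base panel and 50 were custom. The control group and the peritonitis group had 1 section each, so there were no replicates, no test between groups was run, and each difference is one between these sections. The control section held 118899 cells with at least 10 panel counts and 36886230 panel counts in cells, and the peritonitis section held 95864 cells and 29799839 counts. The median was 285 counts per cell in the control section and 289 in the peritonitis section. Negative control probes, which match no transcript, averaged 1.67 and 1.55 CPM each, CPM being counts per 1000000 panel counts. Segmented cells were larger in the peritonitis section, with a median area of 278 square micrometres against 242, and their nuclei covered less of them. In the control section 4 of 96 fields of view had low decoding quality and held 4.65% of the cells, against 0 of 92 fields in the peritonitis section. Ratios are peritonitis over control, followed by exact 95% intervals that cover counting error only.

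Ly6a, Cd300c2 and Slfn5 had the highest ratios of the panel, and genes known from microglia, vessels and meninges were among the others past 1.5. Of 281 genes with at least 100 CPM in one or both sections, 14 were at least 1.5-fold higher and 0 were at least 1.5-fold lower. The median log2 ratio of these genes was 0.06, with quartiles of -0.05 and 0.17. Ly6a, which encodes the interferon-inducible surface protein Sca-1 of brain endothelium, was at 191 CPM in the control section and 744 CPM in the peritonitis section, a ratio of 3.89 (3.79 to 4.0). Slfn5, a Schlafen family gene induced by type I interferon, was at 126 and 320 CPM, a ratio of 2.53 (2.45 to 2.62). Cd300c2, a receptor gene of myeloid cells, had a ratio of 2.59 (2.52 to 2.67). Ly6a lies on chromosome 15 (74994877 to 74998031 in GRCm38, the assembly also called mm10), Slfn5 on chromosome 11 (82951349 to 82964850) and Cd300c2 on the same chromosome (114996721 to 115004261).

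Among the other myeloid genes, Itgam, encoding the integrin chain CD11b, had a ratio of 2.11 (2.06 to 2.16). Ptprc, encoding the leukocyte phosphatase CD45, was 2.06-fold higher (1.99 to 2.14), and C1qc, a subunit of complement C1q made by microglia, 1.76-fold (1.74 to 1.78). Lyz2, the lysozyme gene of macrophages, was 1.96-fold higher (1.92 to 1.99) in the section as a whole but lower in the tissue region led by Pax6 and Top2a, where its ratio was 0.553 (0.517 to 0.591). Gjb2, encoding the gap junction protein connexin 26 of leptomeningeal cells, was 1.88-fold higher (1.81 to 1.95) over the section and lower in the region led by Cux2 and Bhlhe22, at 0.640 (0.585 to 0.70). The remaining 6 of the 14 genes, named after their values were seen, were Trem2 at 1.65, Aldh1a2 and Tyrobp at 1.58, Tmem173 at 1.56, Vwf at 1.53 and Unc13c at 1.5. Trem2 and Tyrobp encode a microglial receptor and its adaptor, Aldh1a2 a retinoic acid synthesising enzyme of meningeal fibroblasts, Tmem173 the innate immune sensor STING and Vwf the von Willebrand factor of endothelium.

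The lowest ratios stayed much closer to 1. Gpr17, a receptor gene of oligodendrocyte precursors about to differentiate, was lowest at 0.825 (0.816 to 0.834). Sox11, expressed in immature neurons, and Top2a, the topoisomerase of dividing cells, had ratios of 0.839 (0.836 to 0.842) and 0.840 (0.830 to 0.850). Nxph3 (0.849), Cplx3 (0.854), Bhlhe22 (0.859) and Car4, encoding a carbonic anhydrase of capillaries (0.860), were also among the 8 lowest. When each section was cut at its median x coordinate, all 14 higher genes had ratios above 1 in the 4 pairings of sides, and 10 of them reached 1.5 in every pairing.

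**Figure D1:**
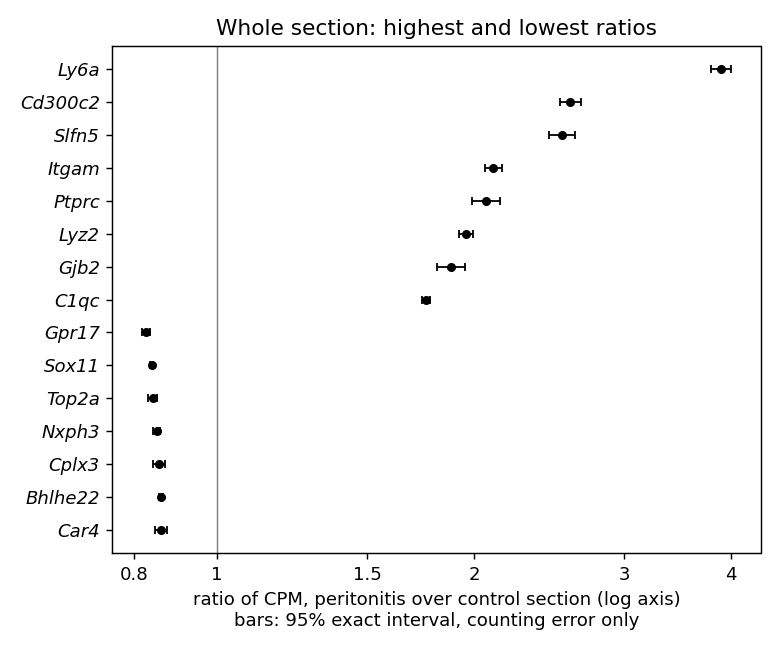
Ratio of CPM in the peritonitis section over the control section (log axis) for the 8 genes with the highest and 7 of the 8 with the lowest ratios over whole sections, with bars for exact 95% intervals covering counting error only. Ly6a stands highest at 3.89 and the lowest gene, Gpr17, lies at 0.825.

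Gene lists fixed from textbook markers had medians above 1 for vascular and immune genes and below 1 for progenitor and neuroblast genes. The division was not confined to these, since the astrocyte and striatal lists also stood at high percentiles (99.4 and 98.3). The oligodendrocyte and ependymal lists (2.12 and 3.44) stood below the neuroblast list (7.85). The vascular inflammation list had a median ratio of 2.53, with Ly6a, Slfn5 and Pglyrp1 (1.23) all higher, and stood at percentile 99.8 among 10000 random panel lists of matched size and expression. This percentile describes these sections and is no test, and these 3 genes are the only members on the panel. Ly6a and Slfn5 were already among the highest genes above. The list median, which is the ratio of Slfn5, therefore adds no separate support. All 11 measured fibroblast genes were higher, with a median of 1.21 (percentile 99.1), among them the abundant Igf2 at 1.15 and Fn1 at 1.1. Of 14 endothelial genes 13 were higher, with a median of 1.17 (percentile 97.4); the tight junction gene Cldn5 was at 1.1 and the VEGF receptor gene Kdr at 1.14, and the exception was Car4. The microglia and macrophage list had a median of 1.24 (percentile 99.0), with 9 of 11 genes higher, led by Cd300c2 and Trem2. Its 2 lower members were P2ry12, the purinergic receptor of resting microglia, at 0.874, and Sla, at 0.934, which cortical neurons also express. The extracellular matrix list reached 1.13 (percentile 93.3), with all 10 genes higher and Col1a1 at 1.39. The activated microglia list reached 1.27 (percentile 96.2, 5 of 6 genes higher), a whole-section value that also depends on the share of microglia-like cells. Within those cells Spp1 (0.658), Igf1 (0.739) and Cd68 (0.822) were lower. Trem2 (0.995) and Cd44 (0.986) were nearly equal there, and of this list only Lyz2 (1.21) was higher.

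Astrocyte genes had a median of 1.12 (percentile 99.4; 5 of 8 higher), with the glutamate transporter gene Slc1a2 at 1.11, the neurotensin receptor gene Ntsr2 at 1.40 and Gfap at 1.21. The 2 measured reactive astrocyte genes were split, with Gfap higher and Cd44 at 0.971, for a median of 1.08 (percentile 60.1). The progenitor and proliferation list had a median of 0.893 (percentile 0.825), with 4 of 5 genes lower, including the stem cell factor Sox2 at 0.875. The neuroblast list stood at 0.902 (percentile 7.85), with Nrep at 0.924 and Cd24a at 0.881, and the oligodendrocyte precursor list at 0.931 (percentile 4.95), with Olig2 at 0.882 and Pdgfra at 1.0. The 2 oligodendrocyte genes that reached 100 CPM, Sox10 and Gjc3, gave 0.916 (percentile 2.12), and the 2 measured ependymal genes, Spag16 and Trp73, 0.997 (percentile 3.44). Sox10 and Gjc3 were also among the top genes of the oligodendrocyte-precursor-like clusters. The myelin gene Mobp, on the panel but below that level, was above 1 in the 4 named classes with at least 100 counts (1.12 to 2.10).

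Neuronal lists had medians on both sides of 1. They were 0.962 for cortical and hippocampal glutamatergic neurons (percentile 7.33), with Neurod6 at 0.864, and 1.02 for subcortical glutamatergic neurons (percentile 48.4), with Necab2 at 1.14. Interneuron genes gave 1.05 (percentile 64.2), with the neuropeptide gene Sst at 1.14, and striatal projection neuron genes 1.07 (percentile 98.3), with Ppp1r1b and the enkephalin gene Penk both at 1.21. Th and Chat, which mark dopaminergic and cholinergic neurons, were both higher, Th at 1.27, for a list median of 1.26 (percentile 72.1). Mural genes had a median of 1.01 (percentile 21.0), with the smooth muscle actin gene Acta2 at 1.39. All 4 immediate early genes were higher, with a median of 1.19 (percentile 85.3) and Fos, which neurons switch on when active, at 1.37. The DNA damage, hypoxia and stress list (0.991, percentile 19.1), the growth factor list (1.05, percentile 52.5) and the axon guidance list (1.03, percentile 39.4) had 2 of 4, 7 of 9 and 8 of 10 genes higher, with Gadd45a at 0.889, Spp1 at 1.31 and Rspo1 at 1.12 among their members. Dividing by the median gene ratio in place of the total put the mural, subcortical and axon guidance medians below 1.

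Microglia-like cells took a larger share of the peritonitis section and progenitor-like cells a smaller one. Microglia-like cells, named by genes such as Siglech, Trem2 and Cd53, made up 2.08% of cells (2.00 to 2.16) in the control section and 3.15% (3.04 to 3.26) in the peritonitis section, a ratio of 1.52 (1.44 to 1.60). With 26 genes that differed between sections left out of the clustering, the ratio was 1.37 (1.29 to 1.45). Progenitor-like cells, led by the germinal zone genes Pax6, Top2a and Gli1, made up 5.45% (5.32 to 5.58) and 3.92% (3.80 to 4.05). Their ratio was 0.720 (0.692 to 0.750), and 0.680 (0.649 to 0.712) without those 26 genes. They had a median of 108 and 91 counts per cell, the lowest of the named classes. This class was 1 cluster whose top 10 genes included Sox11, so immature neurons can be among its cells. Fibroblast-like cells, named by genes of the meninges and vessel sheaths, were at 3.82% and 5.08% (ratio 1.33, 1.27 to 1.38). Endothelial-like cells were at 6.23% and 7.51% (1.21, 1.17 to 1.247). Without the differing genes these ratios were 1.35 and 1.21. 1 of the 3 fibroblast-like clusters, led by Slc13a4, Paqr5 and Igf2, went the other way, with 731 control and 369 peritonitis cells. Its name is uncertain, since 2 of its top 10 genes were fibroblast markers, against 6 and 8 in the other clusters. Paqr5 and Spag16, also among its top genes, were top genes of the cluster lining the ventricle. No listed choroid plexus marker was on the panel to tell such cells apart.

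Oligodendrocyte-precursor-like cells made up 6.53% and 6.02% of cells, a ratio of 0.922 (0.891 to 0.954). Astrocyte-like cells (8.40% and 8.37%, ratio 0.997), cortical glutamatergic-like cells (17.6% and 17.5%, 0.993), interneuron-like cells (5.81% and 5.62%, 0.966) and subcortical glutamatergic-like cells (0.352% and 0.349%, 0.994) had intervals that include 1. Striatal projection neuron-like cells were at 16.6% and 16.0%, a ratio of 0.961 (0.941 to 0.981). Leaving out the fields of low decoding quality took control cells of this class from 19751 to 16114 and all control cells from 118899 to 113373. No peritonitis cells were left out. The resulting ratio of 1.12 (1.1 to 1.15) therefore comes with tissue removed from the control section alone, and is not a share corrected for quality. 1 of the 3 clusters of this class held 2476 control and 67 peritonitis cells. The microglia-like share was higher in 7 of 8 tissue regions, and in the region led by Pax6 and Top2a it was lower, at 1.88% and 1.44% (ratio 0.768, 0.577 to 1.02). The planes of the sections are not given in the sources used here, and 27.1% and 26.5% of cells fell in clusters without a name.

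**Figure D2:**
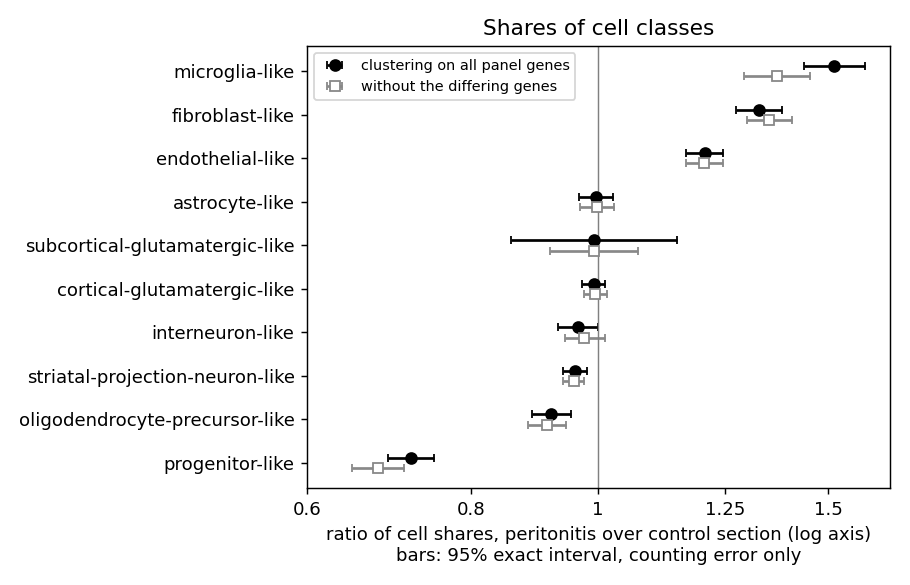
Ratio of the share of cells in each named class, peritonitis over control section (log axis), from clustering on all panel genes (filled circles) and without the differing genes (open squares), with bars for exact 95% intervals covering counting error only. Microglia-like cells lie highest at 1.52 and progenitor-like cells lowest at 0.720.

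**Figure D3:**
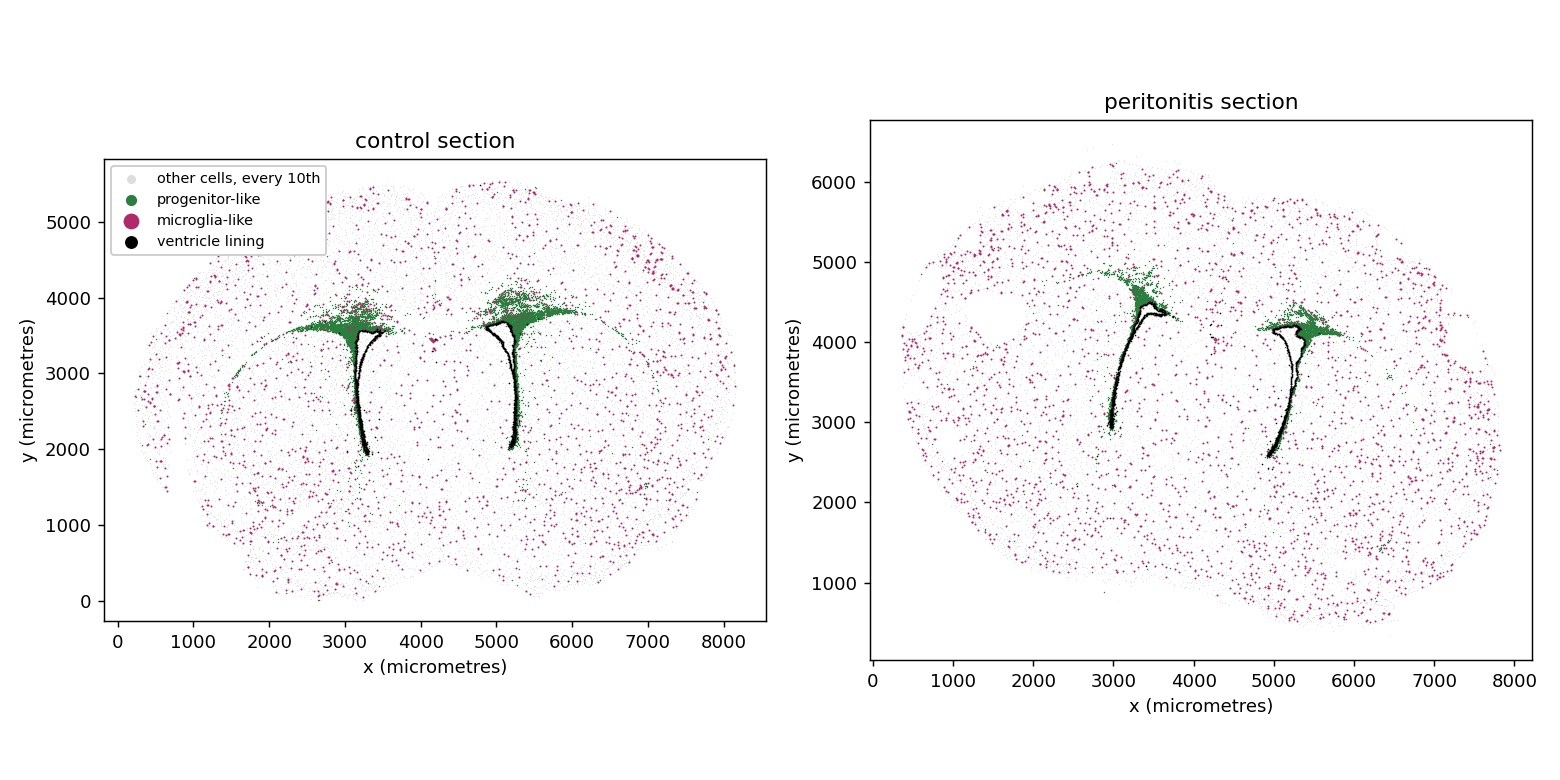
Positions of progenitor-like cells (green), microglia-like cells (magenta) and cells of the ventricle lining cluster (black) in each section, with every 10th other cell in grey and both axes in micrometres. Progenitor-like cells lie around the ventricle lining and extend farther from it in the control section, and microglia-like cells lie throughout both sections.

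Within endothelial-like cells, Ly6a was the gene with the highest ratio, at 2638 CPM in the control section and 7610 CPM in the peritonitis section, a ratio of 2.88 (2.80 to 2.98). Slfn5 was 1.59-fold higher (1.52 to 1.66) and Ntsr2, a gene of astrocytes, whose endfeet wrap vessels, 1.61-fold (1.51 to 1.71). The lowest ratios were those of Carmn, a smooth muscle non-coding RNA, at 0.649 (0.622 to 0.678), of Car4 at 0.675 (0.662 to 0.688), and of the stress gene Gadd45a at 0.715 (0.669 to 0.763). Carmn led 1 of the 4 clusters of the class, which held 1323 control and 960 peritonitis cells. Of 72 genes compared, 3 were at least 1.5-fold higher and 1 lower, and the total of 4 became 12 when the differing genes were left out of the clustering.

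Within microglia-like cells, Slfn5, Msr1 and Ly6a had the highest ratios and Top2a, Tmem144 and P2ry12 the lowest. Slfn5 was at 211 CPM in the control section and 1494 CPM in the peritonitis section, a ratio of 7.09 (5.90 to 8.59). Msr1, the macrophage scavenger receptor gene, was 4.10-fold higher (2.60 to 6.72), from 23 counts and 117 counts, and Ly6a 3.79-fold (3.10 to 4.67). Ly6a was at 192 and 730 CPM in the class, close to its whole-section levels. Transcripts of neighbouring cells can therefore make up its ratio here. In a finer clustering Slfn5 was at 11.05 and Ly6a at 1.83. The fourth gene past 1.5, Cd300c2, was at 1.58. P2ry12 was at 32340 CPM and 18710 CPM, a ratio of 0.579 (0.566 to 0.591), Top2a at 0.523 (0.492 to 0.556) and Tmem144 at 0.570 (0.518 to 0.626). The other genes at least 1.5-fold lower were the replication gene Mcm2 (0.646), Gjc3 (0.633) and the osteopontin gene Spp1 (0.658), making 4 higher and 6 lower of 60 compared. Genes of other cell types moved in the class too, chosen here after their values were seen: the progenitor gene Sox2 was at 0.676 and the oligodendrocyte lineage genes Gpr17 and Olig2 at 0.696 and 0.751, while the endothelial genes Vwf and Cd34 were at 1.57 and 1.396. C1qc (1.04), Trem2 (0.995) and Tyrobp (0.980) had nearly equal levels per microglia-like cell, in contrast to their whole-section ratios.

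Ly6a and Slfn5 were higher outside these classes too. In each of 8 named classes with at least 100 counts in one or both sections, both genes were at least 1.5-fold higher. Ly6a ratios ran from 2.62 in astrocyte-like to 4.85 in fibroblast-like cells, and Slfn5 ratios from 1.59 in endothelial-like to 8.67 (6.30 to 12.2) in striatal projection neuron-like cells, where its level was 8.05 and 69.8 CPM. These class levels can include transcripts of neighbouring cells, since C1qc was also higher in all 10 named classes.

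**Figure D4:**
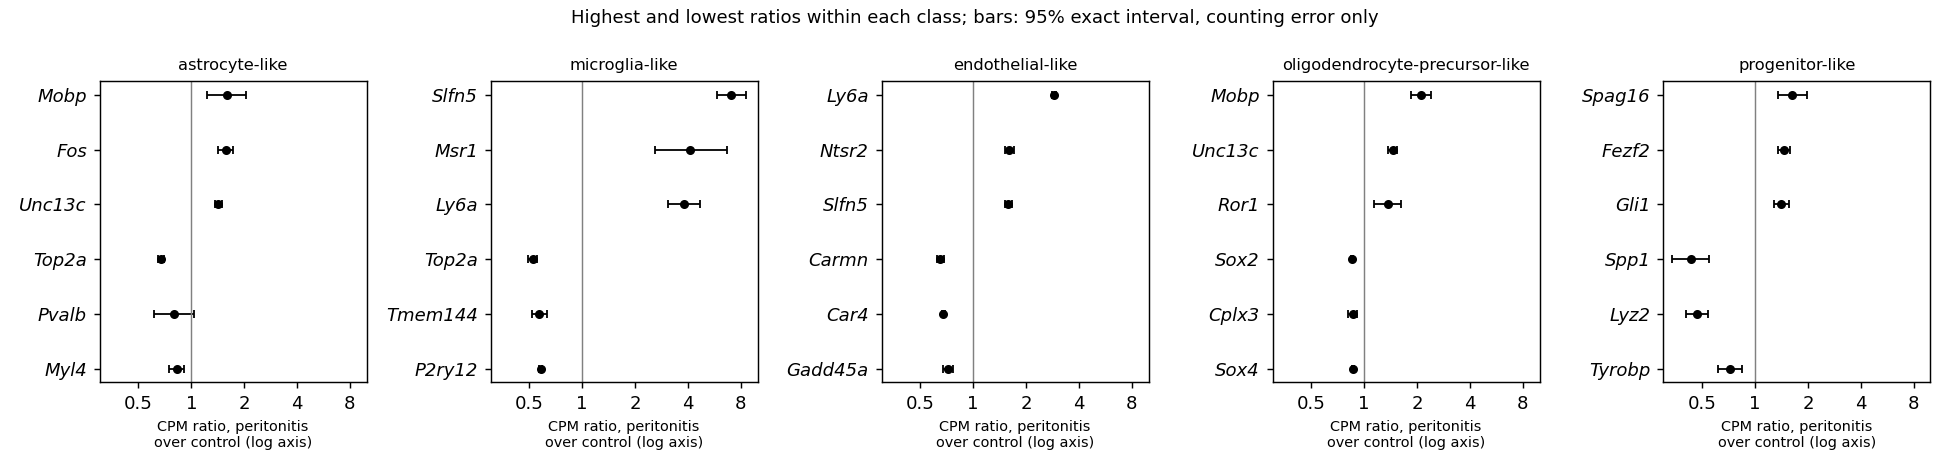
Ratio of CPM within each of 5 cell classes, peritonitis over control section (log axis), for the 3 highest and 3 lowest genes of each class, with bars for exact 95% intervals covering counting error only. Slfn5 in microglia-like cells is highest at 7.09, and Spp1 in progenitor-like cells lowest at 0.430.

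Astrocyte-like cells and oligodendrocyte-precursor-like cells differed little between the sections. In astrocyte-like cells the myelin gene Mobp, at 1.59 (1.23 to 2.06), and Fos, at 1.58 (1.43 to 1.74), were the only genes of 69 past 1.5, followed by the synaptic gene Unc13c at 1.43 (1.36 to 1.5), which was at 0.739 over nuclei alone. Top2a was at 0.669 (0.643 to 0.696), Pvalb at 0.799 (0.615 to 1.03) and Myl4 at 0.827 (0.750 to 0.910). In oligodendrocyte-precursor-like cells Mobp, a gene of myelinating oligodendrocytes, was at 2.10 (1.85 to 2.39), the 1 gene of 69 past 1.5, and between 1.13 and 3.92 over the pairings of sides. Unc13c at 1.45 and Ror1 at 1.36 came next, and Sox2 (0.850), Cplx3 (0.859) and Sox4 (0.863) were lowest.

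In progenitor-like cells the proliferation gene Top2a had a ratio of 1.12 (1.09 to 1.15), while Spp1, Lyz2 and Tyrobp, known from microglia and macrophages, had the lowest ratios. Spp1 was at 0.430 (0.336 to 0.546), Lyz2 at 0.465 (0.402 to 0.537) and Tyrobp at 0.717 (0.613 to 0.837), the last turning to 1.02 in a finer clustering, where Spp1 was at 0.865. Other microglial genes lay on both sides of 1, with Trem2 at 0.804 (0.694 to 0.929), C1qc at 1.06 (0.969 to 1.15) and Cd300c2 at 1.349 (1.05 to 1.73), all chosen after their values were seen. Highest were Spag16, a gene of ciliated ependymal cells, at 1.63 (1.35 to 1.97), the cortical fate gene Fezf2 at 1.46 (1.34 to 1.59) and Gli1, a target of hedgehog signalling, at 1.41 (1.27 to 1.55). Of 71 genes 1 was at least 1.5-fold higher and 2 were lower. Within 75 micrometres of the cluster lining the ventricle lay 2306 of 6475 control and 1929 of 3759 peritonitis cells of this class. The gene ratios can therefore also reflect where the cells lay, which was not tested.

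The response lists within classes took every member with at least 100 counts, and so include genes whose class CPM lay below that of the whole section and whose transcripts can belong to neighbouring cells. The immediate early genes had medians of 1.29 in astrocyte-like, 1.24 in oligodendrocyte-precursor-like, 1.19 in microglia-like, 1.15 in endothelial-like and 1.05 in progenitor-like cells, but 0 of their members reached the whole-section CPM in oligodendrocyte-precursor-like, microglia-like or progenitor-like cells. All 4 measured DNA damage and stress genes were lower in microglia-like cells, with a median of 0.823 (percentile 0.775), and the 3 that reached the whole-section CPM there, Cdkn1a, Igfbp4 and Igfbp5, had a median of 0.856. Their medians were 0.894 in astrocyte-like, 0.902 in endothelial-like, 0.974 in oligodendrocyte-precursor-like and 1.03 in progenitor-like cells. The growth factor list was lowest in microglia-like cells, at 0.858 (percentile 0.930), and lay between 0.930 and 1.03 in the other classes. With only members that reached the whole-section CPM it was at 0.795 in microglia-like cells, from 4 genes, and at 0.667 in progenitor-like cells, from Igfbp5 and Spp1, and 0 members were left in oligodendrocyte-precursor-like cells. Axon guidance medians ran from 0.982 in astrocyte-like to 1.14 in progenitor-like cells, and extracellular matrix medians from 0.982 in progenitor-like to 1.11 in microglia-like cells. Axon guidance in endothelial-like cells had a median of 1.13 but 0.955 for Sema6a, the 1 member that reached the whole-section CPM.

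Near the ventricle the share of progenitor-like cells differed less than over whole sections. Within 150 micrometres of cells with at least 2 ependymal marker counts, they made up 11.4% of cells (11.0 to 11.8) in the control section and 11.0% (10.6 to 11.5) in the peritonitis section, a ratio of 0.967 (0.917 to 1.02). Astrocyte-like cells (0.966) and oligodendrocyte-precursor-like cells (1.02) in this zone had intervals that include 1. Microglia-like cells were at 1.75% and 2.71%, a ratio of 1.55 (1.38 to 1.75). Counts over the neuroblast list had a ratio of 0.903 and those over the progenitor list 0.941. No cluster could be named neuroblast-like or ependymal-like, and only 39.7% and 42.8% of the landmark cells belonged to the cluster that lines the ventricle. Within 150 micrometres of that cluster progenitor-like cells made up 32.9% and 30.9%, a ratio of 0.940 (0.892 to 0.991). Microglia-like cells there made up 1.19% and 1.53%, a ratio of 1.29 (0.990 to 1.67), whose interval includes 1.

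Progenitor-like shares were nearly equal within 75 micrometres of the ventricle wall and lower in the peritonitis section in each band beyond. Measured from the lining cluster, led by the cilia gene Spag16, they made up 35.8% of control cells and 35.3% of peritonitis cells within 75 micrometres, and 27.2% (25.7 to 28.7) and 21.4% (19.8 to 23.1) between 75 and 150 micrometres. Between 150 and 300 micrometres they made up 21.8% (20.8 to 22.9) and 15.7% (14.7 to 16.8), and between 300 and 600 micrometres 11.2% (10.6 to 11.8) and 3.79% (3.42 to 4.19). From 600 to 1200 micrometres the shares were 1.59% and 0.436%, and farther away 0.268% and 0.157%. There were 5.51 progenitor-like cells per lining cell in the control section and 3.36 in the peritonitis section, with 5.41 and 5.61 on the sides of the former and 2.99 and 3.74 on those of the latter. The lining cluster as landmark and the distance bands were chosen after seeing the data. The bands include the 4 control fields of low decoding quality. Both ependymal genes, Spag16 and Trp73, were nearly missing in 1 of these fields, Trp73 alone in another and Spag16 alone in a further field. Lining cells there can go unseen, which would lengthen distances measured in the control section only.

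**Figure D5:**
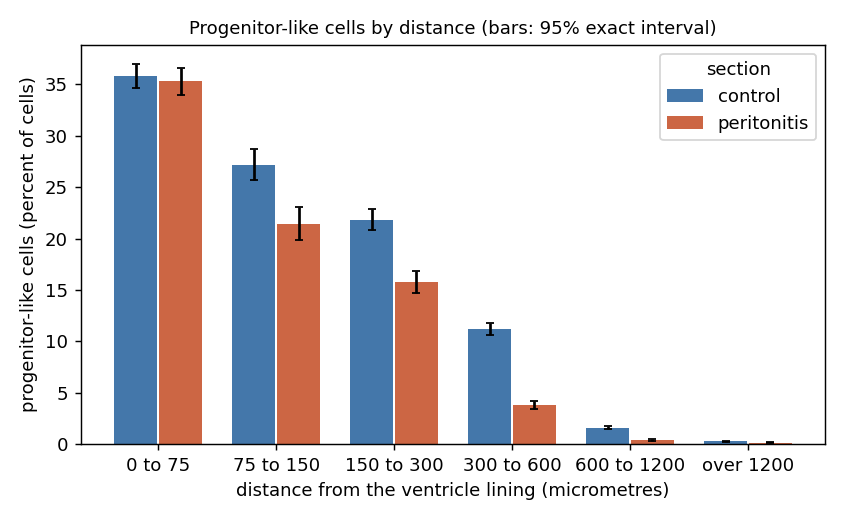
Percent of cells that were progenitor-like by distance from the ventricle lining in micrometres, control section in blue and peritonitis section in orange, with bars for exact 95% binomial intervals. The sections are close within 75 micrometres (35.8% and 35.3%) and apart between 300 and 600 micrometres (11.2% and 3.79%).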

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

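The division into tissue regions behind the Lyz2 and Gjb2 values was chosen only after results were seen, and neither difference between regions was tested.

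Panel transcripts outside segmented cells, which the comparisons as reported left out, made up 1.38% of transcripts of sufficient quality in the control section and 2.35% in the peritonitis section, a ratio of 1.71 (1.70 to 1.71). Counted together with those inside cells, they left all 14 genes at least 1.5-fold higher and added Igfbp6.

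Lyz2 drew attention because its ratio pointed in opposite directions in different tissue regions. It was 3.50 (3.23 to 3.81) in the region led by Nrp2, Nts and Wfs1, at 544 and 1904 CPM, and 0.553 (0.517 to 0.591) in the region led by Pax6, Top2a and Sox9, at 3082 and 1704 CPM. It was above 1 in 7 of 8 regions. Microglia-like cells made up 1.52% and 2.16% of cells in the former region and 1.88% and 1.44% in the latter.

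Gjb2 did likewise, with 6.48 (5.47 to 7.71) in the region led by Nrp2, Nts and Wfs1, at 111 and 721 CPM, and 0.640 (0.585 to 0.70) in the region led by Cux2, Bhlhe22 and Pdzrn3, at 344 and 220 CPM. Gjb2 marks leptomeningeal cells, and the share of fibroblast-like cells lay in the same directions, at 3.17% and 8.63% in the former region (ratio 2.72) and 9.67% and 8.50% in the latter (0.879). In the region led by Cplx3 Gjb2 was at 1.52 and the share at 0.345, on 27 and 7 cells. In the region led by Cd4 they were at 2.09 and 0.541, on 34 and 16 cells. The remaining regions with such cells had both in the same direction.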

How the results depend on the processing

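Leaving out fields of low decoding quality, clustering without the 26 differing genes, the ventricle lining cluster as landmark, the division into tissue regions and the stricter choice of list members within classes were chosen only after results were seen. No paired analysis was possible because each group had 1 section and no test was run. A value counted as moved when it left the counting interval of the reported value, and a count of genes when it differed by over 1.5 times. These intervals are narrow at this depth, so many small moves are counted. Only values whose reported interval excludes 1 were counted as turned when a setting lay on the other side of 1. For a list, the interval runs between the medians of its members' limits. Values whose reported interval includes 1 can cross 1 below without being counted as turned. Depth limits low genes within classes, such as Msr1 in microglia-like cells with 23 and 117 counts. Apart from tissue regions and the periventricular zone, microglia-like shares stayed above 1 (1.28 to 1.58) and progenitor-like shares below 1 (0.626 to 0.794) in each setting run, as did endothelial-like (1.14 to 1.246) and fibroblast-like shares (1.21 to 1.46) above 1. Of class shares 46 moved, 7 turned direction and 67 did neither; of gene lists 66, 7 and 140; of zone values 10, 0 and 24; of counts of genes within classes 7, 0 and 33. Of single genes over whole sections 78 moved and 82 did not, with 0 turned, and within classes 80 moved, 2 turned and 158 did neither. The median ratio scaling lowers the list medians by its construction, and leaving out the low-quality fields removes tissue from the control section only. For the other settings below the cause was not tested.

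The count of 14 genes at least 1.5-fold apart ran from 11 to 19 over other settings of whole sections, and 9 of the 14 remained in each setting run on scaling, counts, quality and fields. Between pairs of section sides it reached 23. Within classes, pairs of sides gave up to 2 genes in oligodendrocyte-precursor-like and 9 in progenitor-like cells and as few as 1 in astrocyte-like cells. Transcripts over nuclei gave 4 in astrocyte-like and 2 in oligodendrocyte-precursor-like cells, resolution 2 gave 1 in progenitor-like cells, and clustering without the differing genes gave 12 in endothelial-like cells.

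Among pairs of sides, share ratios ran from 0.952 to 1.045 for astrocyte-like, 0.831 to 1.16 for cortical glutamatergic-like, 1.21 to 1.46 for fibroblast-like, 0.893 to 1.04 for interneuron-like, 0.647 to 0.794 for progenitor-like and 0.930 to 0.993 for striatal projection neuron-like cells, and the lowest endothelial-like ratio was 1.17. With cells thinned to 50 counts they were 1.04 for astrocyte-like, 1.14 for endothelial-like, 1.03 for interneuron-like, 1.39 for microglia-like and 0.681 for progenitor-like cells. With classes assigned by marker share and no clustering they were 1.045 for astrocyte-like, 0.908 for cortical glutamatergic-like, 1.28 for microglia-like, 0.845 for oligodendrocyte-precursor-like and 0.769 for progenitor-like cells, and 1.06, now above 1, for striatal projection neuron-like cells. Progenitor-like cells were at 0.791 at resolution 0.5 and at 0.626 with at least 50 counts per cell. Striatal projection neuron-like cells were at 0.991 at resolution 2 and 0.992 with genes centred within sections. Without the differing genes, microglia-like cells were at 1.37 and progenitor-like cells at 0.680.

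Without the low-quality fields, shares were 0.947 for cortical glutamatergic-like, 1.27 for fibroblast-like, 0.689 for progenitor-like and 1.12, now above 1, for striatal projection neuron-like cells. List medians were then 0.894 for neuroblast, 1.13 for astrocyte, 1.28 for microglia and macrophage, 1.04 for mural, 0.941 for cortical, 1.01 for subcortical, 1.15 for striatal, 1.32 for dopaminergic and cholinergic, 1.22 for immediate early and 1.18 for extracellular matrix genes.

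Within tissue regions with at least 100 cells of a class in 1 or both sections, share ratios ran from 0.849 to 1.27 for astrocyte-like, 0.969 to 1.02 for cortical glutamatergic-like, 0.683 to 0.903 for progenitor-like and up to 1.03 for interneuron-like cells, and subcortical glutamatergic-like cells had 0.825 in the 1 region with enough of them. In 1 or more regions the direction over the whole section was turned for endothelial-like (0.986 to 1.56), fibroblast-like (0.879 to 2.72), microglia-like (0.768 to 1.89), oligodendrocyte-precursor-like (0.830 to 1.07) and striatal projection neuron-like cells (0.934 to 1.33). In regions with fewer cells ratios spread more widely, as in progenitor-like cells, which were above 1 in 3 of 7 regions, up to 1.33 on 27 cells in each section, and in interneuron-like cells, up to 2.185 on 4 and 7 cells.

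Over nuclei alone, list medians were 0.840 for neuroblast, 0.974 for progenitor, 1.06 for ependymal, 1.13 for astrocyte, 1.04 for reactive astrocyte, 0.944 for oligodendrocyte, 1.29 for microglia and macrophage, 1.075 for endothelial, 2.01 for vascular inflammation, 1.11 for mural, 1.26 for fibroblast, 1.102 for interneuron, 1.38 for dopaminergic and cholinergic, 1.251 for immediate early, 1.08 for axon guidance and 1.252 for extracellular matrix genes, and 0.980, now below 1, for subcortical genes. Within classes, immediate early genes were at 1.47 in astrocyte-like and 1.295 in endothelial-like cells, axon guidance genes at 0.860 and 1.28, and in endothelial-like cells DNA damage genes at 0.870 and matrix genes at 1.297. Growth factors were at 1.11 in progenitor-like cells, and Unc13c turned to 0.739 in astrocyte-like cells.

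With the median gene ratio as scaling factor, list medians were 0.862 for neuroblast, 0.854 for progenitor, 0.954 for ependymal, 1.07 for astrocyte, 1.035 for reactive astrocyte, 0.890 for oligodendrocyte precursor, 0.876 for oligodendrocyte, 1.18 for microglia and macrophage, 1.22 for activated microglia, 1.12 for endothelial, 2.42 for vascular inflammation, 1.16 for fibroblast, 0.920 for cortical, 1.002 for interneuron, 1.02 for striatal, 1.204 for dopaminergic and cholinergic, 1.14 for immediate early, 0.947 for DNA damage, 1.01 for growth factor and 1.08 for matrix genes. Below 1 were now mural (0.963), subcortical (0.979) and axon guidance genes (0.982), the last also in oligodendrocyte-precursor-like cells (0.980). DNA damage genes were at 0.861 in endothelial-like and 0.916 in oligodendrocyte-precursor-like cells. As mean counts per cell in progenitor-like cells, DNA damage genes were at 0.887, growth factors at 0.884 and matrix genes at 0.847, and axon guidance genes turned to 0.982. DNA damage genes and growth factors crossed 1 as well, from 1.029 and 1.025 with intervals that include 1.

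With only list members within classes that reached the whole-section CPM, immediate early genes were at 1.39 in astrocyte-like, growth factors at 0.795 in microglia-like, 0.859 in endothelial-like and 0.667 in progenitor-like, DNA damage genes at 0.859 in endothelial-like and 0.883 in oligodendrocyte-precursor-like, and matrix genes at 0.918 in endothelial-like and 1.27 in oligodendrocyte-precursor-like cells. Axon guidance turned to 0.955 in endothelial-like cells. Growth factors and DNA damage genes (0.993) in progenitor-like cells and matrix genes in endothelial-like cells also fell below 1, from reported intervals that include 1. Fewer members make up these medians, down to 1 gene, and 4 medians had 0 members left and no value.

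In the periventricular zone, progenitor-like cells were at 1.02 and neuroblast counts at 0.911 within 75 micrometres, and progenitor-like cells were at 0.894 and progenitor counts at 0.931 within 300 micrometres. Landmarks with at least 3 marker counts gave 1.1 for astrocyte-like cells, 0.867 for neuroblast and 0.973 for progenitor counts, and the lining cluster 1.203 for astrocyte-like cells, 1.29 for microglia-like cells and 0.924 for neuroblast counts.

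Besides Unc13c, given above, single genes moved over 1.5 times or turned as follows. At resolution 2 in microglia-like cells Slfn5 was at 11.05 and Ly6a at 1.83, and Ly6a was at 2.17 without the differing genes. In progenitor-like cells Spp1 was at 0.865 at resolution 2, 0.693 over nuclei and 0.257 in 1 pair of sides, and Tyrobp turned to 1.02 at resolution 2. In pairs of sides Mobp ran from 1.13 to 3.92 in oligodendrocyte-precursor-like cells, and Pvalb was as low as 0.526 in astrocyte-like cells.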

Other observations

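The tests on the share of endothelial and fibroblast cells, on the length of ventricle wall, on microglia-like cells per area of tissue and on those with Siglech transcripts, the clusterings without differing genes and the split of microglia-like cells by distance were chosen only after results were seen.

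In microglia-like cells Lyz2 was lower in the peritonitis section near the ventricle and higher farther off, and Igf1, Spp1 and P2ry12 were lower in both places, all genes picked after their values were seen. Within 300 micrometres of the lining, 222 control and 226 peritonitis cells of this class had ratios of 0.429 (0.356 to 0.515) for the growth factor gene Igf1, 0.691 (0.644 to 0.742) for Lyz2 and 0.851 (0.756 to 0.958) for Spp1. Igf1, Lyz2 and Spp1 are known from the amoeboid microglia of early postnatal white matter. Farther away the ratios were 0.846 (0.783 to 0.914) for Igf1, 1.39 (1.35 to 1.44) for Lyz2 and 0.627 (0.574 to 0.686) for Spp1. P2ry12 was at 0.613 (0.566 to 0.664) and 0.577 (0.564 to 0.590), and Itgam at 1.51 (1.38 to 1.66) and 1.36 (1.32 to 1.40). Top2a was at 0.90 (0.687 to 1.18) near the lining and 0.506 (0.475 to 0.538) farther away. The differences between the places were not tested.

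Ly6a and Slfn5 were also at least 1.5-fold higher in each of 8 tissue regions, with Ly6a ratios from 3.03 to 11.5 and Slfn5 ratios from 2.14 to 3.84. The highest Ly6a ratio was that of the region led by Pax6 and Top2a, at 107 and 1234 CPM. Sox11 was below 1 in all 8 regions, from 0.722 to 0.915.

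A first pattern is the higher Ly6a and Slfn5 of the peritonitis section. A larger share of vessel and fibroblast cells is argued against as the whole cause by Ly6a within endothelial-like cells, at 2.88. Transcripts of neighbouring cells are argued against for Slfn5 in microglia-like cells by its ratio over nuclei alone, at 10.5 (7.77 to 14.4). For Ly6a in these cells they stay open, since its level of 192 and 730 CPM was close to that of the whole section. Its ratio over nuclei alone, 3.36 (2.44 to 4.69), cannot decide this, because transcripts of neighbouring cells would give a similar ratio. An interferon response to peritonitis may account for both genes, as a hypothesis that no test here decides, and a difference between the animals or sections other than peritonitis stays open and untested.

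A second pattern is the smaller share of progenitor-like cells. Fewer lining cells are argued against as the whole cause by the ratio of progenitor-like cells per lining cell, at 0.610. This ratio cannot decide on less of the wall that bears progenitor-like cells. The lining cells, 1176 and 1119, were not assigned to single walls, and their marker genes were nearly missing in some control fields. A class boundary moved by the genes left out of the clustering is argued against by the share ratio without these, at 0.680. Among the top genes of the progenitor-like cluster, Top2a and Mcm2 were left out, while Pax6, Gli1, Sox2, Gli3 and Sox11 stayed in. The test therefore cannot decide on a boundary moved by genes that stayed in, and this stays open. Another rostrocaudal plane or cutting angle cannot be told apart from an effect of peritonitis, because neither plane is given, and the sides of 1 section differed by up to 1.251-fold in cells per lining cell. No test here bears on how peritonitis would lower the share.

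A further pattern is the larger share of microglia-like cells with lower P2ry12. A moved class boundary is argued against as the whole cause of the share by its ratio of 1.37 without the differing genes, and fewer other cells per area by microglia-like cells per square millimetre of tissue, at a ratio of 1.28, although other cells were at 0.835. Macrophages or leukocytes mixed into the class are argued against as the whole cause by the cells with at least 2 transcripts of the microglial gene Siglech, whose P2ry12 ratio was 0.604 (0.589 to 0.619) and whose share ratio was 1.31 (1.23 to 1.41). A part of the larger share may still come from both together, since Msr1 (4.10), Cd163 (2.60, from 9 and 29 counts) and the B cell gene Ms4a1 (2.52, from 16 and 50 counts) were higher in the class, while the cells with fewer Siglech transcripts, 805 and 1253, decide nothing because Siglech itself was at 0.786. An activated state of microglia in peritonitis is a hypothesis that no test here decides. Of the activated microglia list, Cd68 (0.822), Spp1 (0.658) and Igf1 (0.739) were lower in the class and only Lyz2 (1.21) was higher. Differences between individual animals stay open and untested.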
